A study of Mus musculus with 4 samples.

How the data were processed

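RNA from 4 samples of mouse CD4 T cells was measured on Affymetrix Mouse Genome 430 2.0 arrays, 2 from wildtype and 2 from miR-146a-deficient 2D2 mice. Per the labels, 100 ng of total RNA was labelled with biotin, and cells had been stimulated for 3 days with anti-CD3 and anti-CD28. The labels call the replicates biological but do not say whether they came from separate mice or cultures. The p-values of single genes therefore measure the spread between these samples, moderated by that of other genes. The main p-values of gene lists treat list members as nearly independent, and those for the neighbours of Mir146 count genes. Neither of these measures a spread between mice. Groups were taken from the genotype in the labels.

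The authors deposited 1 linear intensity (MAS5 signal) per probe set and array. The submitters' processing notes name MAS5 and the Transcriptome Analysis Console, with no version. In the deposited table every array has a 2% trimmed mean signal of 500, so the values were already scaled per array. MAS5 detection calls and scanner files were not used here, and scanner date or batch is not given in the sources used here.

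The table holds 45101 probe sets, of which 64 are controls and were left out. Of the other 45037, 34945 have 1 gene symbol, 932 have several and 9160 have none in the annotation used, which pairs probe sets with the platform's gene names. For 34741 of them the gene ID was found in the reference annotation, GRCm38.p6, used only for names and gene order, and 0 symbols were updated. Probe sets with several symbols or none were given no gene name. List members without a probe set named here were left out.

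Signals were transformed as log2(signal + 14.7), the pseudocount being the 25th percentile of all values, so that folds of dim genes are understated. For each of the 18193 genes the probe set with the highest mean log2 value was used; 9010 genes have more than 1 probe set, and probe sets of a gene can differ, which is given beside only some of the named genes. Genes at or above the 40th percentile of mean log2 over probe sets (5.48, a signal of 29.9) were tested, which left 12821. No further normalization between arrays was applied. A linear model was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The moderated test had 8.60 degrees of freedom, of which 2 came from the arrays. A descriptive tier held genes with an unadjusted p below 0.01 and at least a 2-fold change.

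Of the 33 gene lists fixed beforehand, the 30 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists; 11 passed, 9 higher and 2 lower. None passed with an estimated correlation or with fry, limma's rotation test, where the smallest adjusted p were 0.213 and 0.121 and 5 and 7 lists had an unadjusted p below 0.05. The estimated correlations ran from -0.080 (genes near the miR-146a locus) to 0.925 (ribosomal proteins), with 0.311 for the B cell list. Members were also counted when adjusted over the list alone.

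The rule for named genes took, in each direction, the 10 genes with the largest change among those that passed and whose groups did not overlap, filled up from genes with an unadjusted p below 0.01; fixed genes of miR-146a biology; up to 4 members with the smallest p of each list that passed and of the lists of miR-146a targets, NF-kB response, Th17, Th1, Th2 and Treg; and genes near Mir146 and sex-linked genes. The remaining genes that passed, and members that narrowly missed the threshold, were named after their values were seen. The design, lists, naming rule and most alternatives were fixed before the data were examined. Alternatives covered the pseudocount, filter, quantile normalization, median centring, mean of probe sets, variance prior, replicate number as a block, each array left out, every probe set, an adjusted p of 0.10 and other set tests. Leaving out other cell types' markers or the neighbours of Mir146 was added after the data were seen.

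The tests behind the weighed explanations were written after the patterns were seen. The test of whether carried-along B cells supply the cytokine transcripts was first run over both genotypes; after that result was known, forms on the wildtype arrays alone and later on the deficient arrays alone were added, and as these differ the explanation, at first taken as argued against, is left open. Random lists were matched on mean expression, with 10000 draws. The fit was run on data simulated from its own model with independent genes, so these runs could not test that model. In 10 runs over 12821 genes with 200 changed genes each, 7 false calls were made on average, and 0 with no change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.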

Results

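Gene expression was measured in CD4 T cells of 2D2 mice, which carry a transgenic T cell receptor specific for a peptide of myelin oligodendrocyte glycoprotein, with or without the microRNA miR-146a. Naive cells were sorted, stimulated for 3 days on plates coated with anti-CD3 at 5 µg/ml together with anti-CD28 at 1 µg/ml, and their RNA was hybridised to Mouse Genome 430 2.0 arrays. Of the 4 arrays, 2 held wildtype and 2 held miR-146a-deficient cells, each called a biological replicate in the labels. Median signals were 57.7 and 50.2 in the wildtype arrays and 51.4 and 48.7 in the deficient arrays. Over the 12821 genes tested, log2 signals of array pairs correlated across genes with r of 0.986 within each genotype and from 0.984 to 0.985 between genotypes. The number of arrays limits the precision of every value. Group values below are mean signal ± SD over 2 arrays, and changes are log2 differences ± SE, deficient minus wildtype.

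The comparison asks which transcripts differ in stimulated 2D2 T cells when miR-146a, a microRNA known to restrain NF-kB signalling, is missing. No probe set used here is named for the miR-146a gene, Mir146, so the deletion was not checked by its own transcript. Transcripts of B cells and antigen-presenting cells, and of the cytokine genes Ifng, Il2 and Il3, were higher in the deficient cells, and Timd2 was far lower. Ms4a1, which encodes the B cell surface protein CD20, rose 4.75-fold from 198 ± 43 to 994 ± 221. Il2, the T cell growth factor gene, rose 1.98-fold from 1869 ± 251 to 3700 ± 291. Timd2, which encodes a TIM family surface receptor, was 10.9-fold lower, at 117.1 ± 0.47 against 1452 ± 399. Of the 12821 genes, 23 passed limma's moderated test at an adjusted p of 0.05, of which 22 were higher and 1 lower. In all 22 the arrays of the genotypes did not overlap, which selection by that test nearly ensures. Among all tested genes 33.6% did not overlap, where 33.3% would by chance. Beside these differences stood the control ratios of 3' to 5' signal, a sign of RNA quality: each was lower on average in the deficient arrays, at 2.07 ± 0.22 against 2.57 ± 0.24 for the transferrin receptor and 0.762 ± 0.023 against 0.793 ± 0.021 for Gapdh, where the arrays of the genotypes did not overlap, and 1.20 ± 0.08 against 1.24 ± 0.10 for beta-actin, where they did. Without 1 array, a genotype is left with 1 array and the spread comes from the pair of the other genotype, with 1 residual degree of freedom.

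B cell genes formed a large group among them. The list of B cell genes had 16 tested members with a mean change of 1.24 and a median of 1.27; 5 rose when adjusted over all genes and 13 when adjusted over the list alone. Camera called the list higher (adjusted p = 3.3e-30), with adjusted p = 0.213 with an estimated correlation. Besides Ms4a1, Blnk, an adaptor of B cell receptor signalling, rose by 2.11 ± 0.19 (adjusted p = 0.00554) and Cd22, a B cell inhibitory receptor, by 1.74 ± 0.23 (adjusted p = 0.0273). The class II genes H2-Aa and H2-Eb1, used in antigen presentation, rose by 1.49 ± 0.17 and 1.30 ± 0.14. The immunoglobulin genes Igkv9-120, Iglv1, Igkv8-30 and Igk rose by 2.87, 2.24, 1.86 and 1.49. Igkv9-120 started from 19.0 ± 12.7, near background, and its other probe set past the filter, which a pseudocount of 1 selects, gave 0.70 with the pseudocount used here; with a pseudocount of 1 the call was lost (0.87, adjusted p = 0.954). The dimmer of the Cd22 probe sets gave 0.33. With the mean of all probe sets Igkv9-120, Iglv1, Igk and Cd22 had 1.28, 1.88, 1.02 and 1.03 and missed the threshold (adjusted p = 0.390, 0.299, 0.696 and 0.385). Without deficient replicate 2, Cd22, Igk and Igkv9-120 kept changes of 1.47, 1.35 and 2.77 and missed the threshold (adjusted p = 0.0838, 0.0940 and 0.0845). Mzb1, a chaperone of B cells and plasma cells, rose from 1196 ± 186 to 4457 ± 102, a change of 1.89 ± 0.12 (adjusted p = 0.00088). Pou2af1, a transcriptional coactivator of B cells, rose by 1.70 ± 0.24, but missed the threshold with a pseudocount of 1 (1.74, adjusted p = 0.0551) and with the mean of all probe sets (1.70, adjusted p = 0.0745). Spib, Ighm, Cd74 and Cd79b, also on the list, had changes of 1.46, 1.04, 1.23 and 1.55 and missed the threshold over all genes, with adjusted p of 0.0503, 0.0568, 0.0720 and 0.0878. Between the 2 wildtype arrays the B cell list differed too, by a median of 0.34, with 14 of 16 members going the same way.

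Genes on the dendritic cell list were higher as well, but these values do not separate other antigen-presenting cells from B cells. The dendritic cell list (14 tested, mean change 0.78) had 4 members that rose when adjusted over all genes and 8 when adjusted over the list alone, and 4 of its tested members are also on the B cell list. Of those that rose over all genes, H2-Aa and H2-Eb1 are on both lists. Camera called it higher (adjusted p = 2.1e-15), with adjusted p = 0.213 with an estimated correlation. Ccl22, a chemokine of dendritic cells, rose by 1.89 ± 0.16 to 1839 ± 303, and Ly86, which encodes the RP105-associated protein MD-1, rose by 1.87 ± 0.24. Cybb, the NADPH oxidase subunit of phagocytes, rose by 2.25 ± 0.23 from 55.2 ± 2.2 to 319 ± 48, while its other probe sets gave 0.75 and 0.83, and the call was lost with the mean of its probe sets (1.27, adjusted p = 0.180). The list of macrophage and monocyte genes (11 tested, mean change 0.36) did not pass camera (adjusted p = 0.0727). Of its members 6 were higher and 5 lower, and 1 rose over all genes. Its mean was 0.38, 0.35 and 0.38 without wildtype replicate 1, wildtype replicate 2 or deficient replicate 1, each time with 1 array left in that genotype. Ubd, a ubiquitin-like modifier, rose by 2.02 ± 0.23, and Wdfy4, Wdfy1 and Napsa rose by 1.83, 1.83 and 1.39. The other Wdfy4 probe set past the filter gave -0.39, and with the mean of all probe sets Wdfy4, Wdfy1 and Napsa had 0.72, 1.06 and 0.83 and missed the threshold. Wdfy4 also missed it without deficient replicate 2 (1.46, adjusted p = 0.0933). Among the 22 genes that rose, 12 were immunoglobulin genes or stood on a list of another cell type's markers. Mzb1 and Pou2af1, described above as genes of B cells, were not among the 12. With all immunoglobulin genes and listed markers left out before the fit, an alternative chosen after the data were seen, 8 genes passed in place of 23. Mzb1 and Pou2af1 were not left out, so this count is not free of B cell transcripts by design.

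The cytokine genes Ifng, Il2 and Il3 rose, while the cytokine list as a whole (25 tested, mean change 0.06) was not called (adjusted p = 0.492), with 4 members that rose and 2 that fell when adjusted over the list alone. Ifng, the Th1 effector cytokine, rose 1.66-fold from 6671 ± 143 to 11064 ± 516 (adjusted p = 0.0195). Il2 changed by 0.98 ± 0.12 (adjusted p = 0.0208), and Il3, a growth factor for myeloid progenitors, by 1.00 ± 0.14 (adjusted p = 0.0345). Ifng missed the threshold without deficient replicate 1 (0.68, adjusted p = 0.0626) and Il3 without deficient replicate 2 (0.88, adjusted p = 0.0989) and with the mean of probe sets (1.00, adjusted p = 0.0521). Csf2, which encodes GM-CSF, was 12378 ± 1102 against 17765 ± 573, a difference of 0.52 ± 0.09 that did not pass (adjusted p = 0.116). The Th1 list (18 tested, mean change 0.28) had 1 member that rose when adjusted over all genes and 6 when adjusted over the list alone. Camera called it higher (adjusted p = 8.6e-07), with adjusted p = 0.327 with an estimated correlation. Its members with the smallest p after Ifng were Ccl3, Nkg7 and Ccl5, with differences of 0.89, 0.56 and 0.76 that missed the threshold over all genes. The list shares 3 tested members, Nkg7 among them, with the CD8 and cytotoxic cell list and 5 with the chemokine list. Markers of NK cells (mean change 0.58) and of CD8 and cytotoxic cells (0.36) were called higher too, with adjusted p = 0.259 and 0.213 with an estimated correlation. Tbx21, the Th1 master regulator, differed by 0.21 ± 0.11 (adjusted p = 0.953).

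Interferon-response genes were shifted as a list (27 tested, mean change 0.21), with 1 member that rose over all genes and 3 when adjusted over the list alone. Camera called the list higher (adjusted p = 6.0e-07), with adjusted p = 0.213 with an estimated correlation. Gbp2, an interferon-induced GTPase, rose by 1.11 ± 0.10 from 1496 ± 128 to 3235 ± 76 (adjusted p = 0.00692). Iigp1, Gbp3 and Psmb9 had differences of 0.99, 0.63 and 0.31 and did not pass over all genes. The NF-kB response list (28 tested, mean change 0.18) had 1 member, Il2, that rose over all genes and 4 when adjusted over the list alone. Camera called it higher (adjusted p = 6.2e-05), with adjusted p = 0.598 with an estimated correlation. Without wildtype replicate 1 its mean change fell to 0.07 and the call was lost. Traf1, a signalling adaptor induced by NF-kB, had a difference of 0.36 ± 0.10 (adjusted p = 0.486).

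The Th2 list was mixed. Of its 16 tested members, 1 rose over all genes, while 2 rose and 4 fell when adjusted over the list alone. Camera called it lower (adjusted p = 0.0424; mean change -0.12, median -0.20), with adjusted p = 0.418 with an estimated correlation. Il3 and Penk, the enkephalin precursor gene, lay higher by 1.00 and 0.84, the latter at an adjusted p of 0.0505 over all genes. With the median of all values as pseudocount, Penk had 0.83 and an adjusted p of 0.0426. Il5, Gata3, which encodes the Th2 master regulator, and Il4 had differences of -0.66 ± 0.14, -0.34 ± 0.09 and -0.48 ± 0.14, none past the threshold over all genes (adjusted p = 0.226, 0.416 and 0.561). The call was lost in 9 of 18 alternatives, among them no filter, the mean of probe sets and no trend. It was also lost without wildtype replicate 2 (mean -0.05), without deficient replicate 2 (0.02), and when the tested genes around Mir146, which include Il3, Il4 and Il5, were left out of the lists.

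**Figure D1:**
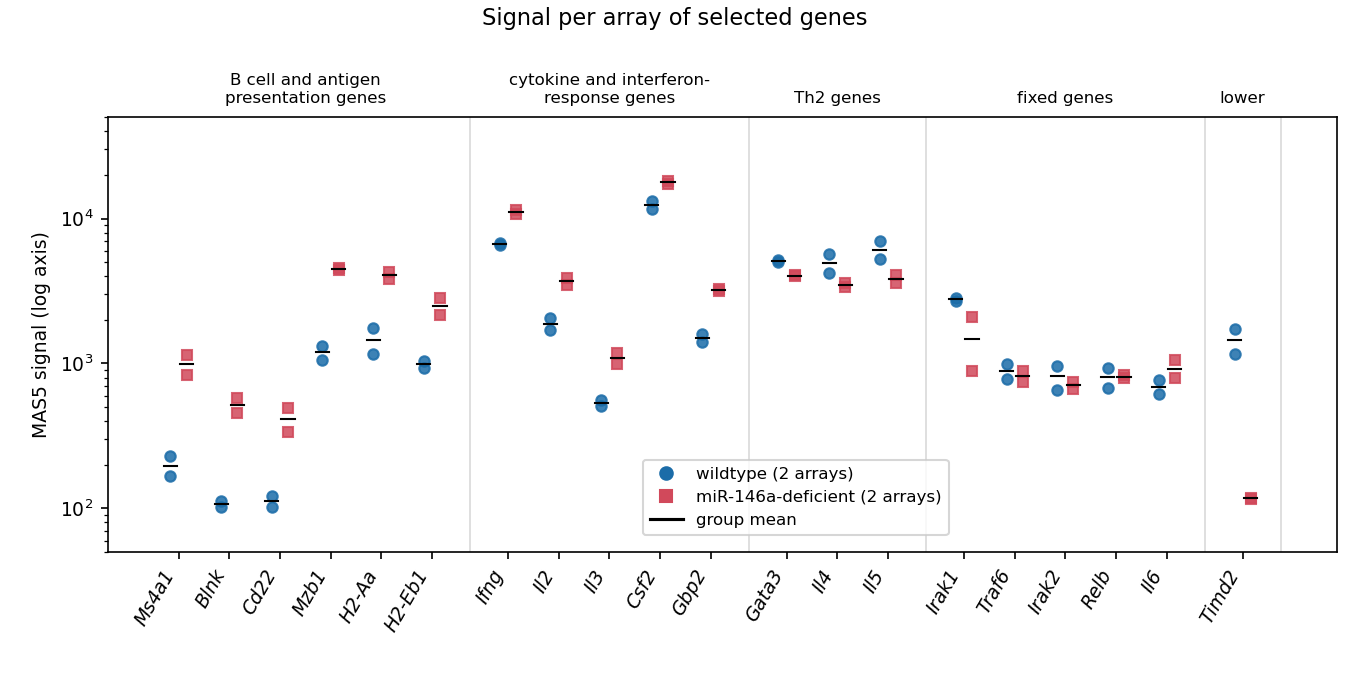
Signal of selected genes in each of the 4 arrays, on a log axis, with wildtype arrays as circles, miR-146a-deficient arrays as squares and the group mean as a black bar. Ms4a1 means were 198 and 994, Ifng means 6671 and 11064, and Timd2 means 1452 and 117.1 in wildtype and deficient arrays; Irak1 has 1 low deficient array, at 885.

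Genes listed beforehand as targets of miR-146a showed no shared shift, with 7 higher, 9 lower and a median change of -0.06. The target list (16 tested) had a mean change of -0.07, none of its members rose or fell over all genes or when adjusted over the list alone, and camera did not call it (adjusted p = 0.484). Traf6 and Irak2, adaptors of Toll-like and IL-1 receptor signalling, differed by -0.11 ± 0.15 and -0.17 ± 0.18. The NF-kB subunit genes Relb and Rel differed by 0.03 ± 0.16 and -0.17 ± 0.15. Irak1, an established target, read -1.03 ± 0.31 on its brightest probe set (adjusted p = 0.621), where deficient replicate 1 stood at 885 and deficient replicate 2 at 2077; without the latter it was -1.63 and passed (adjusted p = 0.00059), a test of the 1 low array in which only the wildtype pair gave the spread. Its other 3 probe sets lay between -0.16 and 0.08. Il6 was 689 ± 110 against 921 ± 184, a difference of 0.41 ± 0.17 that did not pass (adjusted p = 0.921).

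Th17 and Treg genes showed no call over the 4 arrays. The Th17 list (18 tested) had a mean change of 0.09 but a median of -0.04, and camera did not call it (adjusted p = 0.898); none rose over all genes and 2 rose when adjusted over the list alone. Tmem176b and Tmem176a, membrane proteins also found in dendritic cells, had the smallest p, with differences of 1.27 ± 0.25 and 1.11 ± 0.30. Il17a, at 32.0 ± 3.7 against 60.3 ± 45.1, and Il21, at 30.6 ± 12.2 against 47.4 ± 55.6, were close to background. The Treg list (16 tested, mean change -0.05) did not pass (adjusted p = 0.310); without wildtype replicate 1 it was called lower (mean -0.18, adjusted p = 0.00026), with 1 wildtype array left, and without wildtype replicate 2 its mean was 0.08. Foxp3 lay below the filter on dim genes.

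**Figure D2:**
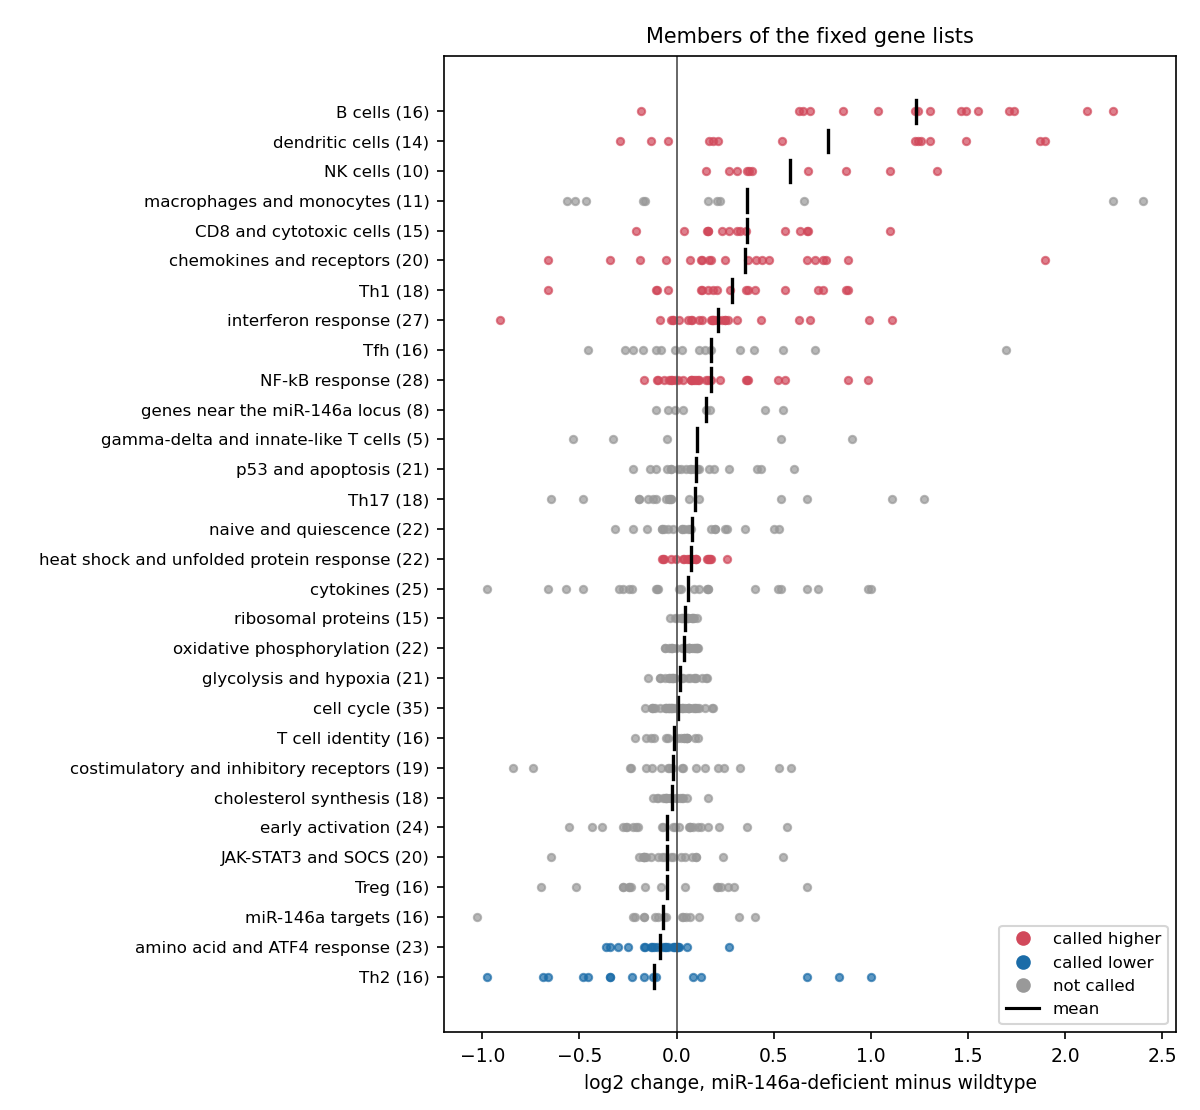
Log2 change, deficient minus wildtype, of each tested member (points) of the 30 gene lists tested, sorted by their mean (black bar), with the number of members in brackets. Colours mark lists that camera called higher (9) or lower (2) with its preset correlation; the B cell list has the highest mean, 1.24.

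Timd2 was the only gene called lower. Its other probe set gave -3.96, and the remaining genes named as lower, Nat8, Slc16a8, Mov10l1, Mamdc2, Klhdc8b, Adam1b, Ak7, 1700012I11Rik and 2410004P03Rik, did not pass and had wildtype means from 64.2 to 117.8. The sex-linked Xist was 10996 ± 750 against 11055 ± 1600, and no Y-linked gene named here passed the filter. Timd2 and several other genes with differences lie around Mir146 on chromosome 11 in gene order. Among the 25 tested genes on each side, 4 had an unadjusted p below 0.01, where 0.79 were expected from the share over all tested genes (one-sided Fisher's exact test, adjusted p = 0.0117). Among 50 on each side it was 4, where 1.58 were expected (adjusted p = 0.0732), and among 100 on each side 14, where 3.15 were expected (adjusted p = 1.0e-05). The further genes of the widest window lay 69 to 98 tested genes from Mir146. The neighbouring Pttg1, the securin gene, read 9037 ± 407 against 13201 ± 558, a difference of 0.55 ± 0.09 that missed the threshold over all genes (adjusted p = 0.0720). Its other probe sets gave 1.30 and 0.91. Pttg1 passed with the mean of its probe sets (0.92, adjusted p = 0.0360) and without wildtype replicate 1 or wildtype replicate 2 (adjusted p = 0.0160 and 0.0027), where 1 wildtype array was left and only the deficient pair gave the spread.

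**Figure D3:**
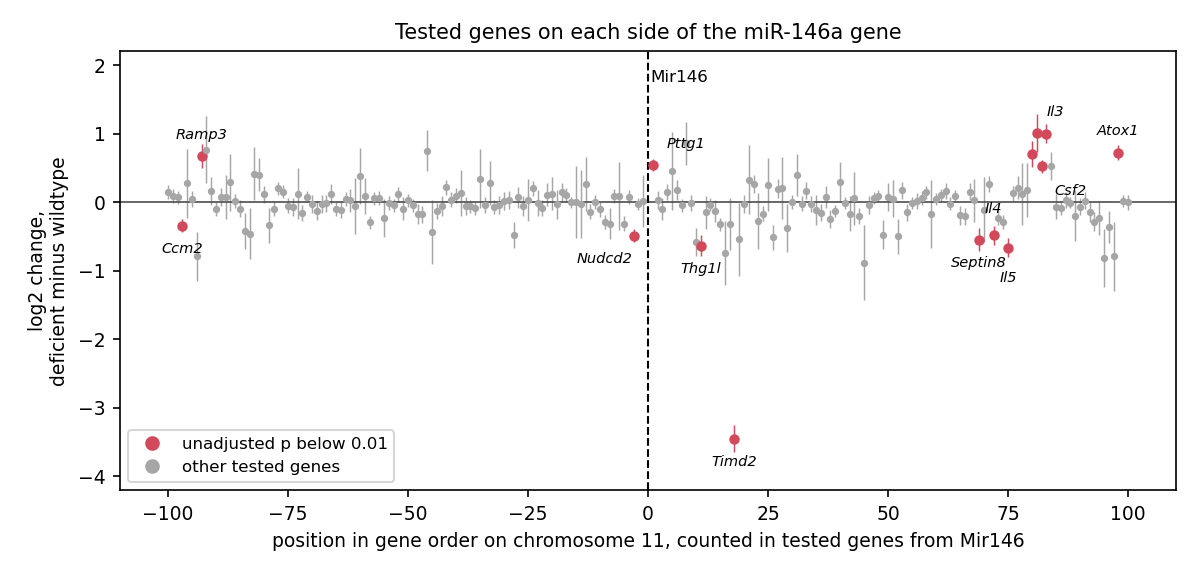
Log2 change ± SE of each tested gene against its place in gene order on chromosome 11, counted in tested genes from Mir146 (dashed line), with genes at an unadjusted p below 0.01 in red. Of the 200 genes shown, 14 are red, among them Timd2 at -3.45 and, farther out, Il4, Il5, Csf2 and Il3.

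The 23 genes stand beside 675 with an unadjusted p below 0.05, where 641 would be expected by chance, and 87 with an unadjusted p below 0.01 and at least a 2-fold change, of which 65 were higher and 22 lower. Limma without the intensity trend called 0 genes (769 with an unadjusted p below 0.05), without a filter 2 genes passed, and leaving out wildtype replicate 1, wildtype replicate 2 or deficient replicate 1 gave 99, 95 or 51. In data simulated from the fit's own model with independent genes, 56.6% of changes of 1 and 82.8% of changes of 2 on the log2 scale used were found. For dim genes such changes are more than 2-fold and 4-fold in signal, and these data cannot test the model itself.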

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

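The tests of carried-along cells, of T cell identity and early activation, and of the neighbours of Mir146 and their probe sets were chosen after the result was seen, as was the use of the planned scalings to weigh an explanation. When every probe set was tested, 8 probe sets without a single gene symbol passed the adjusted p of 0.05, all higher in the deficient arrays; they are outside the comparison of named genes, and 45 of 27022 probe sets passed in all.

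B cell genes were higher in the deficient arrays. Scaling is argued against, since the arrays were already close. Their median log2 signals lay between 8.95 and 8.98 and their upper quartiles of signal between 358 and 370. The list's mean change was 1.27 after quantile normalization and 1.24 after median centring. With arrays this close, neither scaling could change it much. B cells carried along with the sorted T cells may contribute: the list differed by a median of 0.343 between the wildtype arrays, above the upper end of the central 95% of random lists (0.164), but by 0.123 between the deficient arrays, below that end (0.158). Mzb1, H2-Aa and Cd74 had wildtype signals of 1196, 1463 and 1447, and the sort for naive CD4 T cells should remove B cells. Expression by the T cells themselves was not decided by the T cell identity list. Its median change of 0.032 lay inside the central 95% of random lists (-0.031 to 0.082), as a small share of other cells would also leave it. Its mean hung on the arrays used, at -0.091 without wildtype replicate 1 and 0.066 without wildtype replicate 2, with 1 wildtype array left. That list does not weigh the immunoglobulin genes of B cells, Igkv9-120, Iglv1, Igkv8-30 and Igk, which rose by 2.87, 2.24, 1.86 and 1.49.

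Genes with an unadjusted p below 0.01 were more frequent than elsewhere within 25 and within 100 tested genes per side of the miR-146a gene. A chromosome segment that travels with the targeted allele is consistent with this: among 25 tested genes per side the adjusted p was 0.0117, among 50 per side 0.073 and among 100 per side 1.0e-05. Without Timd2 the nearest window gave an unadjusted p of 0.041, and the widest without Il3, Il4, Il5 and Csf2 gave 0.00094. The further genes of the widest window lay apart from the nearest ones. Septin8, Il4, Il5, P4ha2, 4933405E24Rik, Csf2, Il3 and Atox1 stood 69 to 98 tested genes away on 1 side, Ccm2 and Ramp3 97 and 93 on the other. The widest window therefore does not show an unbroken run of changed genes outward from Mir146. A sequence variant under the probes cannot be told apart from a difference in expression: of the 4 genes in the nearest window, Pttg1, Nudcd2, Thg1l and Timd2, 3 had every probe set moving the same way, but where they lie in the transcripts is not known here, and mouse strains were not tested. Hmmr, 4 tested genes from Mir146, was singled out after its values were seen. Its probe sets went opposite ways, from -1.85 (adjusted p = 0.00532) to 0.90 (adjusted p = 0.106) when every probe set was tested. The 4 genes above were picked by their brightest probe set, which in Hmmr read 0.08, so Hmmr was not counted with them. Tpm3, singled out likewise and not among these neighbours, also had opposing probe sets (-1.16 to 0.50). Opposing probe sets thus also occur elsewhere, but how often they do over all genes was not counted.

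Ifng, Il2, Il3 and Csf2 were higher in the deficient arrays, Csf2 without passing. Il3 and Csf2, but not Ifng and Il2, are among the neighbours of Mir146 weighed above, 83 and 82 tested genes away. For Il3 and Csf2 a chromosome segment that travels with the targeted allele therefore cannot be told apart from other causes. Scaling is argued against, as the highest adjusted p of Ifng, Il2 and Il3 under quantile normalization or median centring was 0.029. Of these, median centring could change little, since the arrays' medians were already close. If carried-along B cells supplied these transcripts, they would follow the B cell list between arrays of a genotype; over both genotypes their mean difference was -0.038 where 0.148 was predicted (SE 0.055, or 0.109 if the 4 genes move together), and in forms of this test added after that result was known it was -0.137 where 0.218 was predicted between the wildtype arrays (SE 0.090, or 0.16) and 0.060 where 0.078 was predicted between the deficient arrays (SE 0.090, or 0.16). B cells as the source therefore stay open, since the departure rests on the single pair of wildtype arrays, while between the deficient arrays the value lay within 1 SE of both the prediction and 0, and NK and CD8 cells, whose lists were also higher (mean 0.58 and 0.36) and which the sort for naive CD4 T cells should remove, were not tested as a source. Stronger stimulation overall stays open, since the early activation list had a mean change of -0.047 (adjusted p = 0.465), with members going both ways, and an effect of the missing microRNA on these genes was not tested.

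The 4 arrays allow 3 splits into 2 and 2. Only 1, the real one, gave 23 genes, and the highest of the others gave 0; the splits are too few for a share under 0.05.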

How the results depend on the processing

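The alternatives that leave out other cell types' markers or the neighbours of Mir146 were chosen after the data were seen. All 23 genes were kept with the median as pseudocount, quantile normalization, median centring and a robust prior (29, 29, 31 and 25 genes), while a pseudocount of 1 ended the calls of Igkv9-120 and Pou2af1. The count of 23 moved to 2 without a filter, 14 with the mean of all probe sets, 0 without the intensity trend, 45 with every probe set, 40 at an adjusted p of 0.10, 8 without immunoglobulin genes and other cell types' markers, and 27 to 99 when an array was left out. With the replicate block 14 genes passed, 13 of them shared, and Cd22, Ifng, Igk, Igkv9-120, Iglv1, Il2, Il3, Napsa, Pou2af1 and Wdfy4 were not among them (adjusted p from 0.0520 to 0.109; 0.0704, 0.070 and 0.0856 for Ifng, Il2 and Il3). The labels give the samples only a shared number, and their deviations correlated at 0.05 over genes, though the 3 control ratios of 3' to 5' signal were higher in replicate 2 of both genotypes. The 87 genes by fold and unadjusted p became 46 with the median as pseudocount, 140 without a filter, 55 with a filter at the 60th percentile, 207 with every probe set and 108 to 132 when an array was left out. The 11 lists became 0 with an estimated correlation and 0 with fry. Some results without a call, and the called Th2 and amino acid lists, turned in sign or in camera's direction under an alternative, and the cause was not tested. In some lists only camera's direction turned while the mean kept its sign. This holds for miR-146a targets and for the values of Th17, T cell identity and early activation given next, before the ranges. Th17 had means of 0.060 without a filter, 0.092 at the 60th percentile, and 0.094 on ranks, where the test's direction turned, and T cell identity -0.013 without the trend or on ranks. With the mean of all probe sets, early activation had -0.014, Hspa8 -0.162 and Xist -0.0765, and Xist had -0.0319 after quantile normalization. With each array left out in turn, the ranges were -0.0486 to 0.236 for Th17, -0.0913 to 0.0661 for T cell identity, -0.183 to 0.0109 for the amino acid and ATF4 response, -0.253 to 0.0209 for Th2, -0.128 to -0.0098 for miR-146a targets and -0.180 to 0.0792 for Treg. For genes they were -0.367 to 1.28 for Adra1b, -0.161 to 0.142 for Clint1, -0.114 to 1.19 for Il17a, -0.963 to 1.19 for Il21, -0.439 to 0.102 for Irak2, -0.034 to 0.344 for Manf, -0.280 to 0.0726 for Pwwp2a, -0.191 to 0.254 for Relb, -0.125 to 0.0323 for Rnf145, -0.111 to 0.173 for Slu7, -0.279 to 0.0617 for Traf6 and -0.146 to 0.150 for Xist. Dim genes, near a signal of 29.9, limit what the arrays can show.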

Other observations

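Further lists fixed beforehand also shifted. Chemokine and receptor genes (20 tested, mean change 0.35) were called higher by camera (adjusted p = 2.3e-06), with adjusted p = 0.213 with an estimated correlation; 1 rose over all genes, Ccl22, and 5 when adjusted over the list alone. Cxcr5, the follicle-homing receptor, had a difference of 0.71 ± 0.17 (adjusted p = 0.344). NK cell genes (10 tested, mean change 0.58) were called higher (adjusted p = 3.8e-06), with adjusted p = 0.259 with an estimated correlation, and 4 rose when adjusted over the list alone, 0 over all genes. CD8 and cytotoxic cell genes (15 tested, mean change 0.36), 4 of them shared with the NK list, were called higher (adjusted p = 5.8e-06), with adjusted p = 0.213 with an estimated correlation; 2 rose when adjusted over the list alone and 0 over all genes. The activating receptor gene Klrk1 and the inhibitory Klrc1 had differences of 1.10 ± 0.23 and 1.34 ± 0.29, from wildtype signals of 191 ± 55 and 56.5 ± 6.5, and Gzmb, at 24979 ± 3775 against 31831 ± 1633, one of 0.36 ± 0.11; none of them passed over all genes.

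Shifts in stress lists were small. Heat shock and unfolded protein genes (22 tested, mean change 0.07) were called higher (adjusted p = 0.0287), with adjusted p = 0.569 with an estimated correlation, and the call was lost in 7 of 18 alternatives, among them quantile normalization, the mean of all probe sets, no trend, and leaving out wildtype replicate 1 or deficient replicate 1 (adjusted p = 0.0839 and 0.498). Amino acid and ATF4 response genes (23 tested, mean change -0.09) were called lower (adjusted p = 0.0343), with adjusted p = 0.871 with an estimated correlation; the call was also lost without the trend, without wildtype replicate 2 (mean 0.01) and without deficient replicate 2 (-0.03). In neither did a member pass over all genes or when adjusted over the list alone; Slc1a5, a glutamine transporter gene, differed by -0.34 ± 0.10, and by 0.17 on its other probe set. Camera did not call p53 and apoptosis (mean 0.10, adjusted p = 0.0515), Tfh (0.18, 0.0817), genes near the miR-146a locus (0.15, 0.0817), oxidative phosphorylation (0.04, 0.102), naive and quiescence (0.08, 0.164), ribosomal proteins (0.05, 0.194) or JAK-STAT3 and SOCS genes (-0.05, 0.232). Nor did it call cytokines as a whole (0.06, 0.492), gamma-delta and innate-like T cells (0.11, 0.540), costimulatory and inhibitory receptors (-0.02, 0.544), cell cycle (0.01, 0.605), cholesterol synthesis (-0.02, 0.605), glycolysis and hypoxia (0.02, 0.710) or T cell identity (-0.01, 0.898). For costimulatory and inhibitory receptors the test pointed up while mean and median were negative, and for T cell identity and for glycolysis and hypoxia the mean and median differ in sign. Neutrophil (3), erythroid and platelet (4) and sex-linked (1) lists had too few tested members.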
